A study of Rattus norvegicus with 6 samples.

How the data were processed

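Total RNA from rat soft tissue around implants and from oral mucosa was amplified and labelled with biotin using an Affymetrix 3' expression kit, per the labels' protocols, and each of 6 samples was hybridised to its own array. The deposited table held 31099 probe sets, of which 57 were array controls. Its values were log2 signals that the authors had scaled per array before they deposited them. This reading comes from the values themselves: after conversion to a linear scale, the mean with 2% trimmed at each end was 500.0 on all 6 arrays, and the lowest value on each array was exactly 0 on the log2 scale. Between 150 and 382 probe sets per array stood at that floor. The software, background method and scaling procedure are not given in the sources used here.

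The log2 values were analysed as deposited, without a further normalisation or pseudocount. The planned pseudocount applied to linear values only and was not needed. Probe sets were tested when their mean over all 6 arrays lay above the 40th percentile of the non-control probe sets, a signal of 5.68 on the log2 scale, which left 18625. No detection calls were used. As a guide to dim signals, the 40th percentile of all single values, 5.90, served as a descriptive floor: a gene with a group mean below it is called dim in that group, and its difference is given again with all values below 5.90 raised to 5.90.

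Gene names came from a probe annotation table for the array. It gave 1 symbol for 20832 probe sets and several for 436, and 9780 non-control probe sets were unnamed. Probe sets with several symbols or none were tested but not named. Of the 20832, 20764 matched a gene of the rat GRCr8 annotation by gene number, all under the same symbol, and the other 68 kept the table's symbol. The array's own build is not given, so no coordinates are reported. For each gene the probe set with the highest mean over all 6 arrays was used, which gave 10585 genes.

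Peri-implant soft tissue was compared with oral mucosal tissue, 3 arrays against 3, with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a variance trend, two-sided). P-values were adjusted by the Benjamini-Hochberg method over all probe sets tested, with a threshold of 0.05. Differences are peri-implant minus mucosal on the log2 scale, with the standard error (SE) of the fit. Group values are means ± SD over 3 arrays. Adjusted p-values of single genes come from this limma fit.

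Before the data were examined, 32 gene lists with 1049 entries were fixed for pathways and for the cell types such samples could hold, and 871 entries matched a gene on the array by symbol or synonym. After the matches were inspected, 5 synonyms that named another gene were dropped. Lists with at least 5 measured members, 31 in all, were tested with limma's camera at a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists. Camera asks whether a list is shifted relative to all other genes, so its call refers to the list and not to each member. The single-gene calls of a list's members are also given adjusted over the list alone. One further list, of hair and filiform papilla type keratins, was written after some of the single-gene results had been seen and is used only in the closing section.

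The genes named were chosen by a rule fixed before the data were examined: the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold whose groups did not overlap, up to 4 members with the smallest p in each list described, and 15 genes set in advance. Odam, set in advance, had no probe set named for it alone and was not analysed here. Members that ran against their list, the genes with opposite probe sets and the single genes given for the tests of the closing section were named after their values had been seen, and the alternatives were run for 13 of them. A comparison of bright genes with the highest signal of each array was also added after the data had been seen. Whole profiles were compared by the mean Pearson correlation within groups minus that between groups, with an exact permutation over the 10 splits of 6 arrays into 3 and 3, for which the smallest possible p is 0.1. Array control probe sets were compared with the same exact test, two-sided.

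The fit was tested on simulated data made from the means of the 18625 probe sets and residual spreads of probe sets of like signal, with normal noise. Of 50 probe sets changed at each size, 32% were called in the right direction at a log2 difference of 0.5, 56% at 1, 80% at 2 and 92% at 3. Far fewer probe sets were changed here than the 4188 that passed in the real comparison. The adjusted threshold was therefore stricter in the simulation, and these shares need not hold for the real fit. Among 18372 unchanged probe sets 7 were called. Both lists that were shifted by 0.5 were called, and 0 of the others. The simulated genes varied independently of each other, so this does not show how often camera calls unshifted lists of correlated genes. The arrays number 3 per group, which limits the precision of every value.

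Alternatives covered quantile normalisation, median centring, a floor on dim values, no filter or a stricter filter at the 60th percentile, other variance models, array weights, probe sets without a suffix letter, the mean of a gene's probe sets, other list tests and leaving out each array. The replicate number as a block was fixed in advance as an alternative too. A term for arrays that differed in a hybridisation control, and a fit without the brighter of them, were added after the data had been seen. Figures were drawn with matplotlib 3.10.9.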

Results

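The study compared gene expression in soft tissue that had healed around a dental implant with that in mucosa that had healed over an empty tooth socket. In male Sprague-Dawley rats, an outbred laboratory strain, the upper first molars were removed on both sides at 4 weeks of age, and the left socket alone received a titanium alloy implant. Collection followed 4 weeks later, of the soft tissue around the implant on the left and of the healed mucosa on the right, so tissue type and side of the mouth went together. Each group held 3 arrays. The labels do not say that the samples of a group came from separate rats, so p-values measure the spread between these samples, which may be technical. Median signal was 6.62 to 6.78 on the log2 scale, and 58.3% to 62.4% of the probe sets on an array lay above the dim floor of 5.90.

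Peri-implant soft tissue had higher signals for inflammatory cytokines and chemokines, markers of macrophages and other antigen-presenting cells, and interferon-response genes. It had lower signals for components of hemidesmosomes and the basement membrane, which anchor epithelium to connective tissue. Il1b, which encodes the cytokine interleukin-1β, was 13.2-fold higher, at 11.96 ± 0.10 against 8.24 ± 0.11 in mucosa (SD, n = 3 each; limma adjusted p = 2.38e-11). Cd74, the invariant chain of MHC class II, was 8.88-fold higher (adjusted p = 1.41e-11 in limma). Col17a1, a hemidesmosomal collagen, was 2.80-fold lower (adjusted p = 2.00e-08 in limma).

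Of the 18625 probe sets tested, 4188 (22.5%) passed the threshold, 2243 higher and 1945 lower in peri-implant tissue. In terms of genes, 2767 of 10585 passed, 1606 higher and 1161 lower. A difference of at least 2-fold was seen in 569 of the higher and 226 of the lower genes, and one of at least 8-fold in 48 and 9. Without adjustment, 876 genes were at least 2-fold apart with p under 0.05, 616 higher and 260 lower. The groups did not overlap for 4437 genes (41.9%), where chance gives 10%. Among the 2767 genes, 745 had another tested probe set. It was also called in the same direction for 321 of them and in the opposite direction for 2, Derl1 and Sys1, named after their values were seen.

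Among the 12 largest rises, Cyp2f4, a cytochrome P450 known from airway secretory cells, showed the largest difference as deposited, 7.74 (SE 0.83), at 10.86 ± 0.07 against 3.13 ± 2.46. The mucosal arrays were dim for this gene, and with values raised to the floor the difference was 4.95, smaller than that of Krt36. Krt36, a hair-type keratin found in tongue papillae, stood at 14.08 ± 0.08 against 8.71 ± 0.09, a difference of 5.37, or 41.5-fold, between groups that were both above the floor (adjusted p = 1.77e-13, limma). Saa3, an acute-phase serum amyloid, was higher by 4.73 (SE 0.15) and Pla2g2a, a secreted phospholipase with antibacterial activity, by 4.55 (SE 0.20). Sectm1b was higher by 4.47 and Cfi, complement factor I, by 4.41. The remaining 6 were dim in mucosa: Lcn2 (lipocalin-2, which binds bacterial siderophores), Mfap4 (a microfibril-associated protein), Stra6 (a retinol transporter), Upk1b (a uroplakin), Tspan1 and Batf. Their differences were 5.85, 5.43, 5.25, 4.79, 4.39 and 4.32 as deposited, and 3.59, 3.09, 4.70, 4.35, 2.16 and 2.29 with the floor. For Stra6, which has 3 other probe sets, the difference was 2.15 to 5.60 over its alternatives.

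Among the 12 largest falls as deposited, the metalloproteinase Mmp13, collagenase-3, fell by 3.47 (SE 0.12), from 11.63 ± 0.18 in mucosa to 8.16 ± 0.17. Mmp11 fell by 4.64 and Mmp10 by 4.01, both to dim levels. With the floor they fell by 3.62 and 1.94. Prss23, a serine protease, fell by 4.00 from a mucosal level of 13.30 ± 0.07, and Crip1, a LIM-domain protein, fell by 3.42 from 14.38 ± 0.14. Prxl2a fell by 2.97 and Sema3e, a semaphorin, by 3.08. Slc6a15, Rasd2, Ptgs2os, Dio2 and Gli1, a transcription factor of hedgehog signalling, fell by 3.95, 3.83, 3.00, 2.95 and 2.86 and were dim in peri-implant tissue. With the floor they fell by 2.31, 2.08, 1.63, 1.41 and 1.21. The calls for Mmp10 and Gli1 were lost without the variance trend (adjusted p = 0.0851 and 0.0865 in limma). Over all alternatives the adjusted p ranged from 1.90e-05 to 0.0851 for Mmp10 and from 6.00e-04 to 0.0953 for Gli1.

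**Figure D1:**
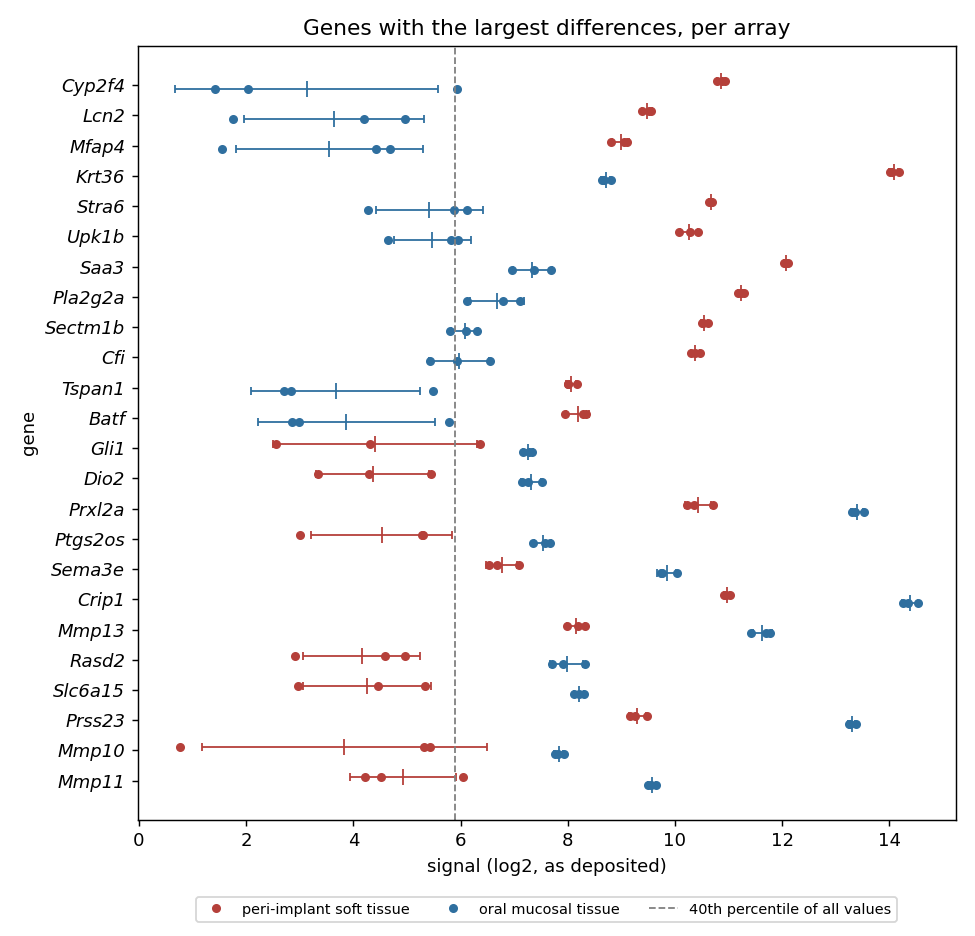
Log2 signal as deposited (x axis) of the 12 genes with the largest rise and the 12 with the largest fall (y axis). Points are single arrays, 3 per group, ticks with bars are means ± SD, and the dashed line is the dim floor of 5.90. The groups do not overlap for any of the 24 genes, and Krt36 lies above the floor in both groups (8.71 and 14.08).

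Acute inflammatory cytokines and neutrophil-attracting chemokines were higher as a list (camera adjusted p = 1.39e-14, and adjusted p = 0.0149 with an estimated correlation). Of 31 measured members 25 were higher, 2 lower and 4 did not pass. The counts were 26 and 2 adjusted over the list alone, and the median difference was 1.65. Cxcl2, a chemokine for neutrophils, was higher by 3.43 (SE 0.09) and Ccl3, a chemokine for monocytes, by 4.29 (SE 0.18). The lower members were Ptgs2, the inducible cyclooxygenase, which fell by 2.12, and Il18, which fell by 1.16. Neutrophil markers were higher by a median of 2.21, with 6 of 8 higher and 0 lower, the same counts adjusted over the list alone. S100a8 and S100a9, the calprotectin subunits, were higher by 1.89 and 2.77, and Csf3r, the receptor for granulocyte colony-stimulating factor, by 2.26. In peri-implant tissue S100a8 and S100a9 lay 0.49 and 0.21 below the highest signal of their arrays, so a ceiling was not excluded and their differences are lower bounds if there was one. This list's adjusted p was 1.21e-04, and adjusted p = 0.0581 with an estimated correlation. Keratinocytes also express S100a8 and S100a9, and 7 genes of the neutrophil list are shared with other lists.

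Macrophage and monocyte markers were higher in 22 of 26 measured members, lower in 1 and did not pass in 3, with a median of 0.97 (camera adjusted p = 1.15e-13, and adjusted p = 0.0149 with an estimated correlation). The counts were again 22 and 1 when adjusted over the list alone. Clec7a, the β-glucan receptor dectin-1, was higher by 2.87 (SE 0.14), Fcgr2b by 2.78 (SE 0.16), Fcer1g by 1.99 (SE 0.08) and the macrophage gene Mpeg1 by 1.69 (SE 0.10). Lyve1, which also marks lymphatic vessels, fell by 1.01. MHC class II and dendritic or Langerhans cell genes were higher in 12 of 16 and lower in 0, with a median of 1.29, and 1.16 to 2.18 over its alternatives (camera adjusted p = 1.98e-10, and adjusted p = 0.0192 with an estimated correlation). There were 13 higher members when adjusted over the list alone. The class II chains RT1-Da, RT1-Bb and RT1-Ba were higher by 2.81, 2.76 and 2.88. That of RT1-Ba was 1.21 to 2.99 over its alternatives, and 1 of its 3 other probe sets was called in the same direction.

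T cell and natural killer cell markers were higher in 12 of 18 members and lower in 1, Thy1, which fibroblasts also express. These counts became 14 and 1 adjusted over the list alone. The median was 1.47, or 1.06 with the floor, and the list's adjusted p was 1.24e-04, and adjusted p = 0.0581 with an estimated correlation. Cd3g, a subunit of the T cell receptor complex, was higher by 2.30 (SE 0.22), Il2rg by 1.83 and Icos by 1.90. Lymphocyte-attracting chemokines and their receptors were higher in 10 of 17 and lower in 1, or 11 and 1 adjusted over the list alone. Their median was 0.80 (camera adjusted p = 0.00879, and adjusted p = 0.181 with an estimated correlation). With the filter at the 60th percentile this list was not called either (adjusted p = 0.258, within a range of 0.00127 to 0.258 over its alternatives). Cxcr4 was higher by 1.88, Cxcl16 by 0.83 and Ccl6 by 0.80, and Cxcl14 fell by 1.42. With the mean of its probe sets Cxcl14 fell by 1.05 and its call was lost (limma adjusted p = 0.0512, within a range of 5.72e-09 to 0.0512 over its alternatives). The list's median was 0.46 to 0.88 over its alternatives. B cell and plasma cell markers, with 2 of 10 higher and 1 lower, were not shifted as a list (adjusted p = 0.341). Jchain, the joining chain of polymeric immunoglobulins, was higher by 3.44, or by 1.71 with the floor. Over the leukocyte and antigen-presentation lists together, 81 genes were measured, of which 56 were higher, 3 lower and 22 did not pass. Erythrocyte genes, a sign of blood in the sample, were higher in 4 of 6 and lower in 1, with a median of 0.64, and were not shifted as a list (adjusted p = 0.216).

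Interferon-response genes were higher in 22 of 32 members and lower in 1, with a median of 1.05 (camera adjusted p = 9.44e-09, and adjusted p = 0.0192 with an estimated correlation). Adjusted over the list alone the counts were 23 and 2. Psmb9, an immunoproteasome subunit, was higher by 2.28 (SE 0.13), Isg15, a ubiquitin-like modifier, by 2.16 (SE 0.14), Ifit3 by 2.57 (SE 0.18) and the guanylate-binding protein Gbp2 by 1.68 (SE 0.11). Bst2, tetherin, fell by 0.58. Antimicrobial and secreted defence genes were higher in 9 of 16 and lower in 2, the same counts adjusted over the list alone. Their median was 0.80 (camera adjusted p = 4.06e-05, and adjusted p = 0.0581 with an estimated correlation), and 0.26 to 1.34 over its alternatives. Scgb1a1, a secretoglobin of airway and other mucosal epithelia, stood at 10.47 against 7.02, higher by 3.45 (SE 0.14). Lpo, lactoperoxidase, was higher by 2.16 (SE 0.10), complement C3 by 3.00 and Serping1, the C1 inhibitor, by 3.48. The lower members were Clu and Slpi, a protease inhibitor of mucosal secretions, which fell by 0.58 and 0.59. The call for Slpi was lost in 2 of 19 alternatives (limma adjusted p from 8.82e-06 to 0.0658).

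**Figure D2:**
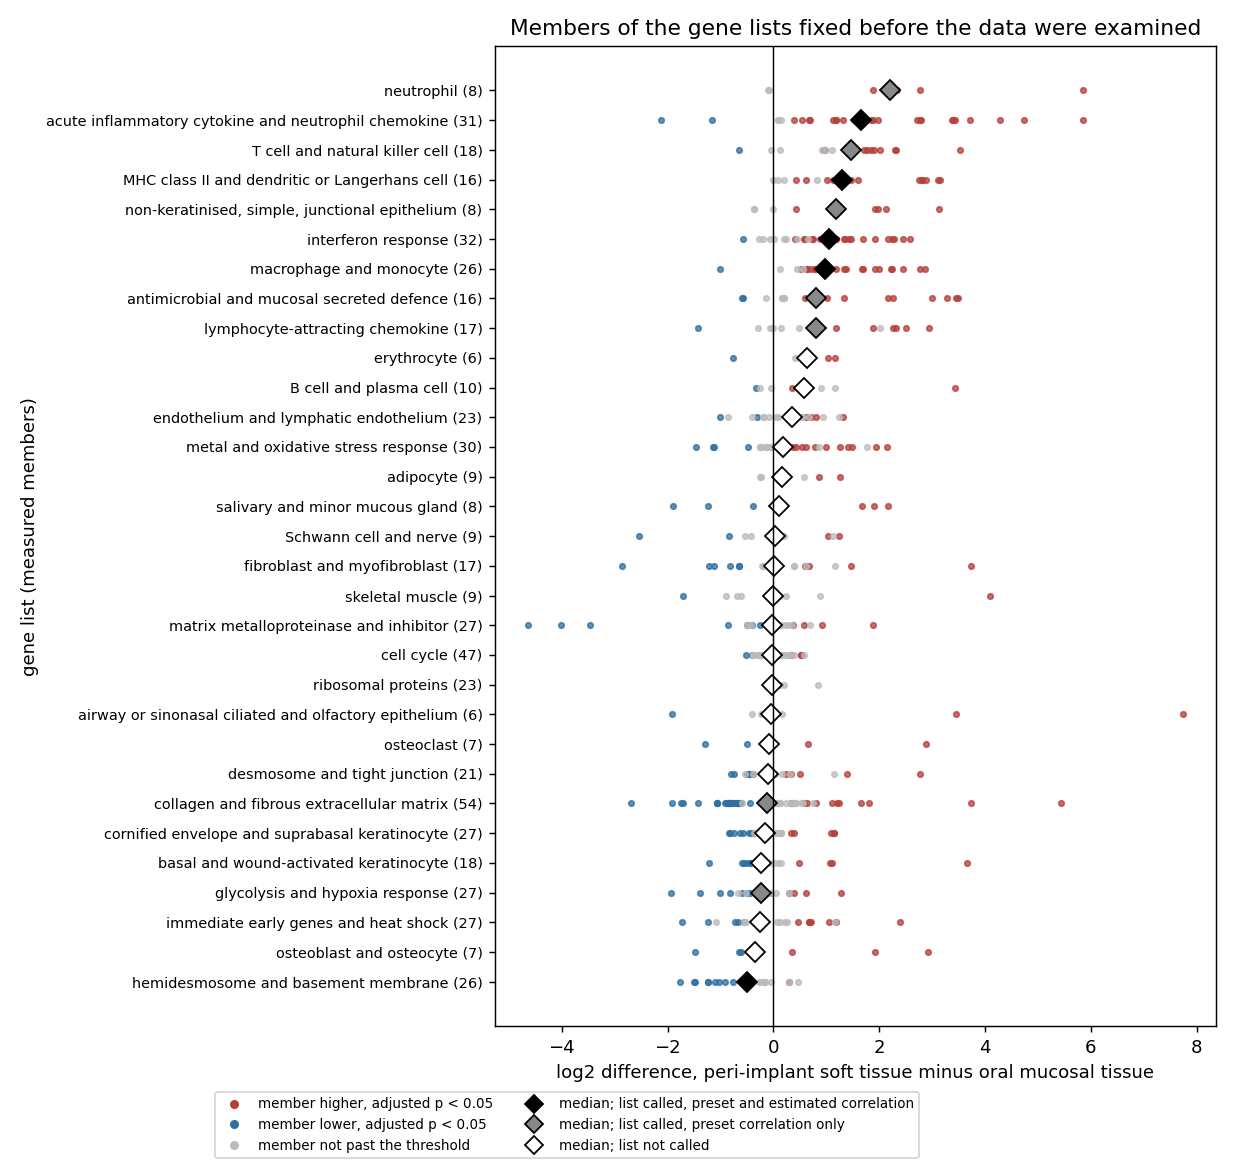
Log2 difference, peri-implant minus mucosal (x axis), of the measured members of 31 gene lists (y axis). Small points are genes, coloured by their limma call, and diamonds are list medians, filled by whether the list passed camera. The lists called with both correlations have medians of 1.65, 1.29, 1.05, 0.97 and -0.50.

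Hemidesmosome and basement membrane genes were lower in 14 of 26 members and higher in 1, with a median of -0.50 (camera adjusted p = 2.87e-09, and adjusted p = 0.0242 with an estimated correlation). Adjusted over the list alone the counts were 15 and 1. Col17a1 fell by 1.49 (SE 0.08), Dst, which encodes the hemidesmosomal plakin BPAG1, by 1.23 (SE 0.07), the anchoring fibril collagen Col7a1 by 1.51 (SE 0.10) and the laminin β3 chain Lamb3 by 1.10 (SE 0.07). Itgb4, the hemidesmosomal integrin β subunit, fell by 0.45 (SE 0.09, limma adjusted p = 0.00291). Its call was lost without the variance trend (limma adjusted p = 0.0588, within a range of 8.66e-04 to 0.0588 over its alternatives). Cd151, a tetraspanin that binds laminin receptors, was the member that was higher, by 0.30, and its call was lost in 2 of 19 alternatives (limma adjusted p from 0.00154 to 0.0945).

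Collagen and fibrous matrix genes moved both ways, with 24 of 54 lower, 12 higher and 18 not past the threshold. Adjusted over the list alone the counts were 26 and 14. The median was -0.12 and the list was called lower (camera adjusted p = 0.00195, and adjusted p = 0.126 with an estimated correlation). It was also not called by camera on ranks (adjusted p = 0.118, within a range of 5.76e-06 to 0.126 over its alternatives), and its median was -0.63 to 0.02 over these. Tnc, tenascin-C, fell by 2.69 (SE 0.09), Col5a3 by 1.75, Postn, periostin, by 1.06 and Col1a1, the main fibrillar collagen chain, by 0.83 (SE 0.07). Ltbp1, which binds latent TGF-β, was higher by 1.20, and the list also holds Mfap4. Metalloproteinases and their inhibitors were higher in 4 of 27 and lower in 7 and were not shifted as a list (adjusted p = 0.501). Besides the falls of Mmp13, Mmp11 and Mmp10, Ctss, a lysosomal cathepsin of antigen-presenting cells, was higher by 1.89 and the macrophage elastase Mmp12 by 0.93. Mmp9 stood at 9.46 ± 0.19 against 9.55 ± 0.06 (limma adjusted p = 0.640). Fibroblast and myofibroblast genes were higher in 4 of 17 and lower in 6 (list adjusted p = 0.539). Glycolysis and hypoxia genes were lower in 9 of 27 and higher in 4, with a median of -0.24 (camera adjusted p = 5.50e-04, and adjusted p = 0.173 with an estimated correlation). In this list 14 were lower and 4 higher adjusted over the list alone. Adm, adrenomedullin, fell by 1.93, Bnip3 by 1.39, Ndrg1 by 1.02 and Pfkp by 0.83.

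Keratins and other genes of simple, non-keratinised or junctional epithelium were called higher as a list, with 5 of 8 members higher, 0 lower and 3 not past the threshold, and a median of 1.17 (camera adjusted p = 2.14e-04, and adjusted p = 0.0581 with an estimated correlation). The counts were the same adjusted over the list alone, and camera on ranks did not call the list (adjusted p = 0.0742, within a range of 1.02e-05 to 0.0742 over its alternatives). The median ranged from -0.0038 without a filter to 1.92 over its alternatives. Krt4, a keratin of non-keratinised mucosa, was higher by 3.12 (SE 0.08), Krt7 by 2.12, Krt23 by 1.97 and Krt19 by 1.92 (SE 0.11). The members that did not pass were the keratins Krt8, Krt20 and Krt13. Krt13, also of non-keratinised mucosa, stood at 16.16 ± 0.32 against 16.17 ± 0.30 (limma adjusted p = 0.991). Its difference of -0.0038 turned to 0.19 under quantile normalisation, where it passed (limma adjusted p = 0.00620, within a range of 0.00620 to 0.994 over its alternatives). Basal and wound-activated keratinocyte genes went both ways, 4 of 18 higher and 6 lower (list adjusted p = 0.497). Krt15, a basal keratin, was higher by 3.65 (SE 0.07), and the growth factors Areg and Hbegf by 1.10 and 1.08, while the basal keratin Krt5 fell by 0.50 (SE 0.09) and S100a4 by 1.21. Krt14, the partner of Krt5, stood at 15.71 ± 0.33 against 15.95 ± 0.44 (limma adjusted p = 0.463).

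Cornified envelope genes were likewise mixed, 5 of 27 higher and 8 lower (list adjusted p = 0.186). Without mucosal array 1 this list was called lower (adjusted p = 0.0242, within a range of 0.0242 to 0.705 over its alternatives). Krt1, Sprr2d and Sprr3 were higher by 1.14, 1.10 and 1.14, and the desmocollin Dsc1 fell by 0.85. Krt10, the partner of Krt1, stood at 16.20 ± 0.29 against 16.52 ± 0.42 (limma adjusted p = 0.289). Without mucosal array 1 its difference of -0.32 became -0.56 and passed (limma adjusted p = 0.0223, within a range of 0.0223 to 0.600 over its alternatives). Krt10, Krt13 and Krt14 lay within 1 log2 unit of the highest signal of their arrays. There 67 genes mostly rose and fell with that highest signal from array to array (median correlation within groups 0.984, above 0.9 for 58 genes). A ceiling was not excluded, so the small differences of these keratins are not measured equalities. The cornified envelope, basal keratinocyte, desmosome and ribosomal lists hold such genes as well. Sprr3 (in peri-implant tissue), Slpi (in both tissues) and Krt5 (in mucosa) are others. The change of Krt13 under quantile normalisation falls under the same limit. Desmosome and tight junction genes were higher in 5 of 21 and lower in 6 (list adjusted p = 0.496). Cldn8 was higher by 2.77, and Pkp3 and Cldn1 fell by 0.80 and 0.74. Cell cycle genes, with 42 of 47 not past the threshold, and ribosomal protein genes, with 23 of 23 not past it, were not shifted as lists (adjusted p = 0.539 and 0.671). For lists that were not called, the counts adjusted over the list alone were 5 higher and 7 lower for metalloproteinases, 5 and 7 for fibroblasts, and 4 and 6 for basal keratinocytes. They were 5 and 8 for the cornified envelope, 6 and 7 for desmosomes, 4 and 1 for B cells, 5 and 1 for erythrocytes, 1 and 0 for the cell cycle, and 0 and 0 for ribosomal proteins. In 9 of the 31 lists the median, the mean and the direction of the test differed in sign, and 0 of these were called.

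Whole profiles separated the tissues. The correlation between arrays was 0.975 to 0.981 within peri-implant tissue, 0.965 to 0.974 within mucosa and 0.931 to 0.945 between them. The separation was 0.036, larger than in the other splits of the 6 arrays (exact permutation p = 0.1, the smallest possible, n = 3 each). The first principal component carried 56.5% of the variance and parted the groups.

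Control probe sets differed between the groups as well. The 3' minus 5' difference of beta-actin, which grows as RNA degrades or labelling shortens, was 3.98 ± 0.03 on peri-implant arrays and 3.22 ± 0.27 on mucosal arrays (exact permutation p = 0.1, adjusted p = 0.2 over 10 controls, n = 3 each). That of Gapdh was 0.18 ± 0.04 and 0.17 ± 0.04, and that of hexokinase 3.07 ± 1.49 and 0.85 ± 0.65. The 5S rRNA level was 9.10 ± 0.09 and 9.71 ± 0.26, and the 3' level of the Dap spike 10.08 ± 0.22 and 10.60 ± 0.07 (exact permutation p = 0.1 for hexokinase and for each of these levels, adjusted p = 0.2). The ranges of the actin difference did not overlap between the groups, so it follows the same split of arrays as tissue type. The BioB hybridisation spike split the arrays another way: those numbered 1 in either group stood at 10.91 and 11.16, and the 4 numbered 2 and 3 at 8.19 to 8.65. Within the brighter and the dimmer set the median difference was 1.62 and 1.59 for the inflammatory list, 1.07 and 0.97 for macrophages, 1.31 and 1.24 for MHC class II, 0.97 and 0.95 for interferon response, and -0.39 and -0.53 for hemidesmosomes. With the 4 dimmer arrays alone 2530 probe sets passed, and 2486 of them (98.3%) had the same direction between the arrays numbered 1. With the set as a block 4030 passed.

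**Figure D3:**
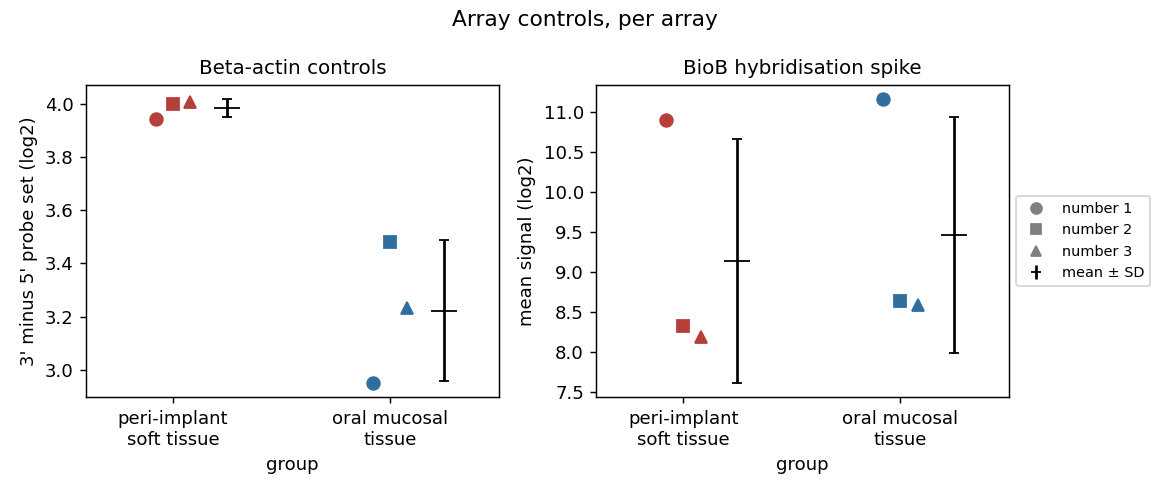
Control signals per array (y axes, log2) in each group (x axes), with the sample number as the symbol and means ± SD in black, n = 3 per group. The beta-actin 3' minus 5' difference is 3.94 to 4.01 on peri-implant arrays and 2.95 to 3.48 on mucosal arrays, and BioB is brighter on the arrays numbered 1 in both groups.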

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

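The fit without the brighter BioB arrays and the BioB block were chosen after the data had been seen. With arrays numbered 2 and 3 alone 2530 probe sets passed in place of 4188, with fewer arrays; 2457 of them were among the 4188, all in the same direction. Under the other alternatives the count was 2864 to 4696. Leaving out an array gave 3071 to 4044 probe sets, 840 to 909 genes at least 2-fold apart, 12 to 13 lists and a separation of 0.033 to 0.039. The filter at the 60th percentile, which tests fewer genes, left 465 genes at least 2-fold apart in place of 876. Camera with an estimated correlation called 5 lists in place of 12, and fry, which does not compare a list with other genes, called 23. The separation was 0.0154 without a filter and 0.362 over the 1000 probe sets with the highest variance, against 0.036. Krt13 turned from a difference of -0.0038 to 0.19 under quantile normalisation, and the ribosomal list, median 0.070, was called higher there; the cause was not tested. Fry called higher the basal keratinocyte, osteoblast and osteoclast lists. Their medians of -0.23, -0.36 and -0.088 are below 0, but their means of 0.091, 0.30 and 0.21 are above 0. Whether this accounts for the calls was not tested. Of 135 genes chosen by the naming rule and past the threshold 117 passed under every alternative run, as did 11 of 13 genes named after their values were seen. Among the largest changes, 7 of the 12 largest rises and 7 of the 12 largest falls rest on a group mean below the floor.

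The replicate block gave 4076 probe sets against 4188, with 3906 shared, and changed no list call. Same-numbered samples did not deviate together (correlations of 0.013, -0.079 and 0.027, against -0.063 to 0.050 for different numbers). No label says that a number is one rat, so the numbers were not read as pairs. With 3 arrays per group this check cannot show that samples of the 2 groups came from different rats. The planned pseudocount was not run because the values were already logarithmic.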

Other observations

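The airway and muscle tests below were chosen after the results had been seen. The hair and filiform papilla list was written after some of the single-gene results had been seen. Several lists outside the main themes held single genes that moved strongly. Metal and oxidative stress genes were higher in 11 of 30 and lower in 4 and were not shifted as a list (adjusted p = 0.193). Sod2, the mitochondrial superoxide dismutase, was higher by 1.94 (SE 0.08), Aldh3a1 by 2.15 and the cystine transporter Slc7a11 by 1.49, while Akr1b8 fell by 1.15. Immediate early and heat shock genes were higher in 7 of 27 and lower in 9 (list adjusted p = 0.539), with Fos higher by 2.39 and Dusp1 by 1.18. Over its alternatives Dusp1 was higher by 0.67 to 1.22, and its other probe set was not called. Hspa1a fell by 0.73 and Jund fell by 0.67. Of 7 osteoblast and osteocyte genes 3 were higher and 3 lower (list adjusted p = 0.914). Spp1, osteopontin, was higher by 2.91 (SE 0.08), and Ibsp, bone sialoprotein, fell by 1.49. Of 7 osteoclast genes 2 were higher and 2 lower (list adjusted p = 0.914). Car2, a carbonic anhydrase, was higher by 2.87 (SE 0.08) and Nfatc1 fell by 1.29.

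Gland, vessel, nerve, fat, airway and muscle genes gave no shifted list. Of 8 salivary and mucous gland genes 3 were higher, Elf5 by 1.89 among them, and 3 lower, with Aqp5 falling by 1.90 (list adjusted p = 0.671). Endothelial genes were higher in 4 of 23 and lower in 2 (list adjusted p = 0.452). Of 9 Schwann cell and nerve genes 2 were higher and 2 lower (list adjusted p = 0.671), and Pmp22, a myelin gene that other cells also express, fell by 2.54. Of 9 adipocyte genes 2 were higher, Fabp4 by 1.26 (list adjusted p = 0.348). Of 6 airway genes tested 2 were higher and 1 lower (list adjusted p = 0.914), and of 9 skeletal muscle genes tested 1 was higher and 1 lower (list adjusted p = 0.632). Mast cell and eosinophil genes had 3 measured members and were not tested: Siglec5 and Hpgds, both dim in mucosa, were higher by 3.30 and 1.57, or by 2.80 and 1.07 with the floor, and Tpsb2, a mast cell tryptase, had a difference of -0.80 (limma adjusted p = 0.0990). The call for Hpgds was lost in 6 of 18 alternatives (limma adjusted p from 0.00307 to 0.0959). The counts adjusted over the list alone were 14 higher and 6 lower for metal and oxidative stress, 8 and 10 for immediate early genes, 3 and 3 for osteoblasts, and 2 and 2 for osteoclasts. They were 3 and 3 for glands, 4 and 2 for endothelium, 3 and 2 for nerve, 2 and 0 for fat, 2 and 2 for airway, 1 and 1 for muscle, and 2 and 1 for mast cells.

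Of the leukocyte lists, that of macrophages was called higher with either correlation, those of neutrophils and T cells lost their call with an estimated one (adjusted p = 0.0581 each) and that of B cells was not called, and both technical explanations were tested on the macrophage list only. A smaller share of keratinocytes alone would raise the markers of every other cell type alike. However, the macrophage median exceeded the endothelial median by 0.61 (bootstrap 95% interval over genes 0.31 to 1.38, 25 and 22 genes). The endothelial list's own median was 0.36. That of desmosomes and tight junctions was -0.10, but a ceiling on its bright members, such as Dsp, was not excluded. Among other lists the median was 0.0046 for fibroblasts, 0.023 for nerve, 0.17 for fat and 0.64 for erythrocytes. These lists were thus not raised alike. A part played by keratinocyte share was still not excluded, and the interval does not measure the spread between samples. A general rise of dim probe sets on the peri-implant arrays would lift lists of like signal, but the macrophage median of 0.97 stood at percentile 100 of 10000 random lists matched on mean signal, 95% of which lay between -0.11 and 0.21. The beta-actin difference and the 3' level of the Dap spike follow the same split of arrays as the groups. A contribution of RNA quality, of labelling or of the side of the mouth was therefore not separated from tissue type. A greater number of macrophages around the implant, or a higher expression per cell, stays open as a hypothesis that these data do not test.

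Scgb1a1 and Cyp2f4, both known from airway secretory cells, were higher by 3.45 and 7.74. Cyp2f4 was dim in mucosa, and its difference was 4.95 with the floor. If airway or sinonasal epithelium had been carried into the peri-implant samples in quantity, its other transcripts would be higher too. The other 18 genes of the airway list on the array had a median difference of -0.23 (bootstrap 95% interval -0.84 to -0.03), and 16 of them had a peri-implant mean below the floor. These include the nasal gland genes Bpifa1 at 5.78 and Obp1f at 2.91 and the ciliated cell gene Foxj1 at 4.56. Because 15 of the 18 were below the floor in both groups, the median mostly compares dim values. A small carry-over was not excluded. An oral or peri-implant epithelial source of both transcripts may account for the pattern; it was not tested, nor was whether each probe set detects its transcript.

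Krt36 and Krtap14l, a hair keratin-associated protein, were higher by 5.37 and 3.28. Tongue or other muscle carried into these samples does not show as a general rise of muscle genes: the 48 on the array had a median difference of -0.44 (bootstrap 95% interval -0.76 to -0.12), and 40 of them had a peri-implant mean below the floor, although Mb, dim in mucosa, was higher by 4.10, or by 2.45 with the floor, and Myh1 stood at 11.78 against 11.79 in mucosa. Of the 48 muscle genes, 37 were below the floor in both groups, so a small carry-over of muscle was not excluded. Hair-bearing skin or tongue epithelium stays open. The other 10 hair and filiform papilla type genes on the array had a median difference of 0.0689 (bootstrap 95% interval -0.43 to 1.43). Of these, Krtap1-5 was dim in both groups and Padi3 in peri-implant tissue. Krt86, Krt33b and Tchh were higher by 2.85, 1.49 and 1.43, while S100a3 and Msx2 fell by 2.63 and 0.33. A change of epithelial differentiation at the implant may equally give this mixture, and no test here separates it from carried tissue.

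The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05, and the real grouping gave the largest count in 1 of them for each result. It gave 4188 probe sets against at most 0 in another split, 876 genes at least 2-fold apart against at most 35, and 12 lists against at most 11. The other splits set arrays of both tissues against each other unequally and so carry part of the tissue difference. Each of their sides mixes the tissues, so the tissue difference also widens the spread within sides. That lowers the number of probe sets that pass, so the counts of these splits are not those expected by chance. With an estimated correlation the real grouping gave 5 lists and the others at most 0, and the inflammatory list's median was 1.65 against at most 0.61.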
